A study of Arabidopsis thaliana with 9 samples.

How the data were processed

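Rosette leaves of Arabidopsis thaliana Col-0 plants, grown at 22 °C with 8 h of light for 5 to 6 weeks per the labels, were taken in 3 groups of 3 libraries: untreated, mock treated and treated with Alternaria brassicicola. Per the labels, 1000000 spores per ml were sprayed in 0.01% Silwet L-77, and leaves were harvested 3 days later. Polyadenylated RNA was taken from 3 µg of total RNA, and libraries were made with ScriptSeq v2 and size-selected to 250 to 650 bp. The labels give no content for the mock liquid and no harvest time for mock or untreated plants.

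Per the submitters' processing notes, reads were checked with FastQC and aligned to TAIR10 with TopHat2 2.0.12, counted with HTSeq and compared with DESeq2 1.8.2. The HTSeq version, the strand setting, the annotation release and the DESeq2 design formula are not given in the sources used here. The authors' deposited count files hold raw counts per gene, 1 file per library. The authors' 6 deposited comparison tables hold log2 fold changes with their standard errors and, per the file headers, DESeq2 p-values and adjusted p-values. Their sign was checked against the counts, and a positive value means higher in the group named second. Gene names came from the TAIR10.1 reference annotation, used for names only, which named 28932 of 33610 listed genes (86.1%), and the other 4678 kept their locus.

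Lines that are not genes (reads without a feature, ambiguous or not unique) made up 7.73 to 11.2% of a library's counts and were left out. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 22019. Counts were scaled by the trimmed mean of M values (TMM) and fitted with edgeR 4.0.16 in R 4.3.3, all 9 libraries in 1 model with 1 mean per group and 6 residual degrees of freedom. Each comparison used the quasi-likelihood F test and a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 change divided by the square root of F. Log2 CPM used a prior count of 2. The biological coefficient of variation was 0.107.

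The tests of the comparisons, the 32 gene lists and all alternatives but 1 were chosen before the data were examined, and the closing part says which of its tests were chosen later. Lists covered camalexin, tryptophan, indole and aliphatic glucosinolates, jasmonate synthesis and its MYC and ethylene-shared branches, salicylic acid, pattern recognition, WRKY factors, antifungal proteins, detoxification, phenylpropanoids, flavonoids, light harvesting, the Calvin cycle, chlorophyll, senescence, abscisic acid, touch, the clock, growth, small RNA machinery, microRNA targets, microRNA and TAS precursors, markers of guard cells, epidermis, vessels, dividing cells, root and flower, and reference genes. Of 691 distinct loci in them 650 were tested and 41 were not, 34 were renamed after the annotation, and 17 belong to more than 1 list. Lists of at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists with Benjamini-Hochberg, then with an estimated correlation. Fry tests whether a set's genes move, on balance, in 1 direction, its Mixed test asks for change in either direction, and neither compares with other genes.

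Genes were named by a rule written beforehand. Among nuclear genes past the threshold with a mean of at least 5 CPM and groups that do not overlap (10% of genes by chance), the 6 largest rises and 6 largest falls of each comparison were eligible, with up to 4 members of each list with the largest change, and PR1, PDF1.2a, PAD3, ICS1, VSP2, AGO1, AGO2 and DCL1 whatever their p. Clock genes set in phase groups and the families of the closing part were chosen after values were seen.

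The procedure was tested on simulated counts drawn from the measured means, library sizes and dispersions, with 200 genes changed and a list of 20 more raised 1.5-fold. For Alternaria against mock, Alternaria against untreated and mock against untreated it recovered 50.7%, 43.3% and 49.3% of genes changed 1.5-fold, 79.1%, 80.6% and 76.1% of those changed 2-fold and 93.9%, 90.9% and 92.4% of those changed 4-fold. False calls made up 7.34%, 6.75% and 7.65%. Camera called 0 of 20 unchanged lists, but the draws held no correlation between genes, so lists of related genes stay untested. Alternatives were RLE and upper-quartile scaling, other filters, DESeq2 1.42.0, limma-voom, 6-library fits, a replicate block, a fold limit, organelle genes left out, and each library left out in turn (9 leave-outs). Tables and figures used numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.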

Results

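Messenger RNA was sequenced from Col-0 rosette leaves in 3 groups: untreated, mock treated, and sprayed with spores of Alternaria brassicicola, a fungus that feeds on killed leaf tissue. Each group held 3 libraries, which the labels call biological replicates. Reads assigned to genes numbered 22713147, 30902196 and 24487509 in untreated replicates 1, 2 and 3, 35822935, 28826970 and 36061529 in the mock replicates, and 33738207, 28851200 and 28758293 in the Alternaria replicates. Between 28226 and 29609 of 33610 listed genes had at least 1 read in a library, and 22019 genes were tested. At these depths a count of 0 in a library allows up to 3 counts, which is 0.0832 to 0.139 counts per 1000000 reads (CPM) and covers counting error only. Genes of the plastid chromosome held 5.51% ± 0.733 of the reads in genes in untreated leaves, 4.06% ± 0.472 in mock leaves and 2.97% ± 0.287 in Alternaria leaves (mean ± SD, n = 3 per group).

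Alternaria libraries stood apart from both other groups on component 1 of a principal component analysis, and mock libraries lay between. Across all tested genes, Pearson's r of log2 CPM was 0.984 to 0.989 within the untreated group, 0.990 to 0.991 within the mock group and 0.989 to 0.990 within the Alternaria group. Between groups it was 0.969 to 0.981 for untreated against mock, 0.921 to 0.941 for mock against Alternaria and 0.876 to 0.920 for untreated against Alternaria (r across genes, which are not independent replicates). Component 1 held 74.3% of the variance. On component 2 (10.1%) mock libraries lay outside both other groups, at -40.3 to -28.7 against 16.2 to 33.9 in untreated and 3.58 to 17.5 in Alternaria libraries. Untreated replicate 1 stood apart from its group on component 3 (4.04% of the variance), at 45.4 against -12.2 and -21.0, and values that rest on it are given where they occur.

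**Figure D1:**
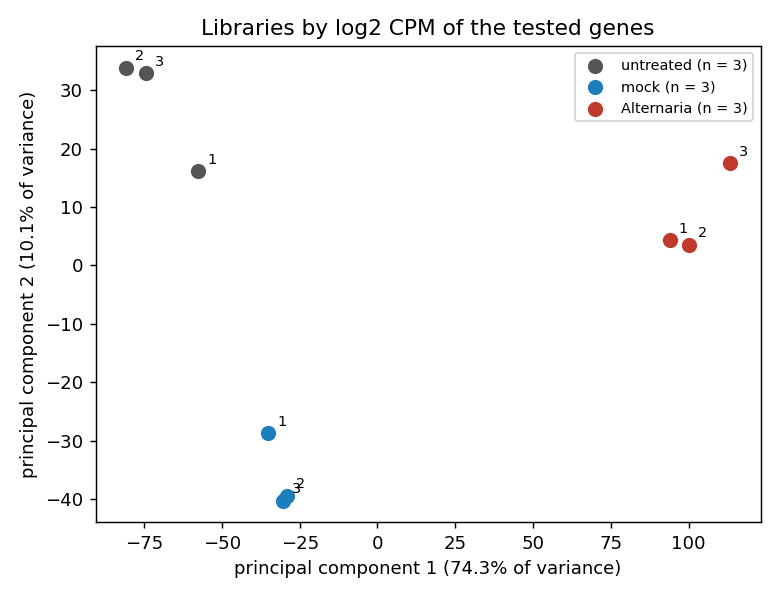
Principal components 1 and 2 of log2 CPM over 22019 tested genes (component scores, no unit), 1 point per library, coloured by group with 3 libraries each. Component 1 (74.3%) ran from -80.9 to -57.7 in untreated, -35.1 to -29.2 in mock and 94.0 to 113 in Alternaria libraries.

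Alternaria against mock asks what the fungus adds, if harvest hours (not given) matched. The salicylic acid marker PR1 (AT2G14610) rose 149.8-fold, from 11.3 ± 4.69 CPM in mock leaves to 1703 ± 496 CPM in Alternaria leaves (mean ± SD, n = 3), against 5.73 ± 3.57 CPM in untreated leaves (log2 change 7.23 ± 0.42, SE). AT1G26390, which encodes a berberine bridge enzyme-like oxidase, rose by 6.94 ± 0.32 on the log2 scale, and AT3G28510, a nucleoside triphosphatase gene, rose by 6.71 ± 0.32. The antifungal defensin gene PDF1.2a (AT5G44420) rose by 5.86 ± 0.24, from 5.62 ± 1.99 to 324 ± 70.3 CPM. The deepest falls were those of AT3G15310.1 (-4.16 ± 0.24), the cysteine protease gene AT2G27420 (-3.90 ± 0.16), the cell wall hydrolase gene XTH31 (AT3G44990) (-3.70 ± 0.25) and the transporter gene AT5G62730 (-3.24 ± 0.19), beside AT1G13609 at a lower level (-4.18 ± 0.36, from 9.76 ± 3.29 to 0.518 ± 0.314 CPM). The largest adjusted p among these 9 genes was 7.3e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg), with no overlap between groups. AT1G13609 was -4.83 without Alternaria replicate 1.

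In edgeR's quasi-likelihood test 12241 of 22019 genes (55.6%) passed a Benjamini-Hochberg adjusted p of 0.05, 6489 higher and 5752 lower in Alternaria leaves. Under upper-quartile scaling the split was 4937 higher and 8114 lower (13051 in all), since that scaling moves the median log2 change of all tested genes by -0.175, so the sign of smaller changes rests on the scaling. At least 2-fold changes numbered 3752, 2571 up and 1181 down, and at least 4-fold changes 1090 up and 105 down. The authors' deposited table had 11672 genes at an adjusted p under 0.05 (6272 up, 5400 down), and 11480 of them were also called by edgeR, 0 in the opposite direction. Across genes the log2 changes of the authors' deposited table and of edgeR had r = 0.997.

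Genes that make camalexin, the indole phytoalexin of this plant, rose nearly as a block. CYP71A13 (AT2G30770) rose by 4.79 ± 0.31 on the log2 scale, PAD3 (AT3G26830), which encodes the last enzyme of the pathway, by 3.52 ± 0.54. CYP82C2 (AT4G31970), which acts on a separate indole branch but was put in this list, rose by 5.83 ± 0.36. Tryptophan, the precursor, is made with TSA1 (AT3G54640) and ASA1 (AT5G05730), which rose by 2.06 ± 0.17 and 1.68 ± 0.14. Indole glucosinolate genes split, with IGMT1 (AT1G21100) and CYP81F2 (AT5G57220) up by 3.07 ± 0.23 and 3.06 ± 0.28. MYB34 (AT5G60890), 1 of the regulators of this pathway, fell (-1.35 ± 0.16). The regulator MYB29 (AT5G07690) and the transporter gene BAT5 (AT4G12030) of aliphatic glucosinolates, which are made from methionine, fell (-1.61 ± 0.18 and -1.18 ± 0.14). All 10 passed edgeR's quasi-likelihood test, with a largest Benjamini-Hochberg adjusted p of 1.1e-04, with no overlap between groups. Of 14 camalexin genes, 13 rose (13 adjusted over the list alone), median log2 change 2.68 (camera adjusted p = 1.6e-05, adjusted p = 0.220 with an estimated correlation). Among 10 tryptophan synthesis genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone) and the median log2 change was 1.14 (camera adjusted p = 0.0192, adjusted p = 0.433 with an estimated correlation). The 15 indole glucosinolate genes had a median log2 change of 0.77 (camera adjusted p = 0.0999, adjusted p = 0.517 with an estimated correlation), and 9 rose and 3 fell (9 and 3 adjusted over the list alone). Of 20 aliphatic glucosinolate genes, 1 rose and 17 fell (1 and 17 adjusted over the list alone), median log2 change -0.96 (camera adjusted p = 2.2e-05, adjusted p = 0.421 with an estimated correlation), with 0 rises and 18 falls under upper-quartile scaling. The tryptophan synthesis genes had 1 fall without Alternaria replicate 1 and the indole glucosinolate genes had a camera adjusted p of 0.0373 without untreated replicate 1. The aliphatic glucosinolate genes had 0 rises in 5 of 9 leave-outs.

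Jasmonate and salicylic acid genes, often opposed in leaf defence, rose side by side. Among jasmonate synthesis genes LOX4 (AT1G72520) rose by 2.46 ± 0.21 and AOC3 (AT3G25780) by 2.13 ± 0.22. In the branch of the response run by MYC factors, the jasmonate-hydroxylating oxygenase gene JRG21 (AT3G55970), the aminotransferase gene TAT3 (AT2G24850) and the transcription factor gene NAC055 (AT3G15500) rose by 5.03 ± 0.26, 4.58 ± 0.29 and 4.39 ± 0.24, whereas the wound marker VSP2 (AT5G24770) measured -0.30 ± 0.46 and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.604). The branch shared with ethylene holds the PDF1 defensin genes, of which PDF1.2c (AT5G44430) and PDF1.3 (AT2G26010) measured 6.58 ± 0.42 and 6.86 ± 0.41. These copies are nearly identical in sequence, so their separate values are uncertain, as are those of CYP71A13, IGMT1, AOC2 and VSP2, which have close copies. On the salicylic acid side DLO1 (AT4G10500), FMO1 (AT1G19250) and the synthesis gene ICS1 (AT1G74710) rose by 6.20 ± 0.25, 5.65 ± 0.34 and 1.85 ± 0.19. Each of these 8 genes had a Benjamini-Hochberg adjusted p of at most 4.2e-06 in edgeR's quasi-likelihood test, with no overlap between groups. Of 13 jasmonate synthesis genes, 10 rose (11 up and 1 down adjusted over the list alone), median log2 change 1.12 (camera adjusted p = 0.00117, adjusted p = 0.251 with an estimated correlation), with 10 rises and 2 falls under upper-quartile scaling. Among 26 MYC-branch genes, 21 rose and 1 fell (21 and 1 adjusted over the list alone) and the median log2 change was 2.23 (camera adjusted p = 1.7e-07, adjusted p = 0.246 with an estimated correlation). The 16 genes of the branch shared with ethylene had a median log2 change of 3.18 (camera adjusted p = 1.3e-07, adjusted p = 0.188 with an estimated correlation), and 15 rose (15 adjusted over the list alone). Of 27 salicylic acid genes, 26 rose and 1 fell (26 and 1 adjusted over the list alone), median log2 change 3.10 (camera adjusted p = 6.0e-12, adjusted p = 0.188 with an estimated correlation). The MYC-branch genes had 0 falls in 3 of 9 leave-outs.

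Receptor and early signalling genes rose too, among them NHL10 (AT2G35980) (5.45 ± 0.25), the wall-associated kinase gene WAKL10 (AT1G79680) (4.25 ± 0.19) and the immune receptor gene RLP23 (AT2G32680) (3.91 ± 0.39). WRKY factors, regulators of defence genes, were led by WRKY75 (AT5G13080) at 5.35 ± 0.31 and WRKY62 (AT5G01900) at 5.18 ± 0.20. Genes of proteins that act on fungal or plant walls included the pectin methylesterase gene PME17 (AT2G45220) (6.43 ± 0.25), the glucanase gene AT4G16260 (5.44 ± 0.26) and the chitinase gene CHI (AT2G43570) (5.16 ± 0.43). The alternative oxidase gene AOX1D (AT1G32350) and the glutathione transferase gene GSTU3 (AT2G29470) stood for detoxification, with rises of 5.66 ± 0.29 and 5.34 ± 0.37. Touch and wound genes that respond within minutes, such as CML37 (AT5G42380) and WRKY40 (AT1G80840), rose by 3.79 ± 0.35 and 3.18 ± 0.22. In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p of these 12 genes reached at most 2.6e-06, with no overlap between groups. Of 27 pattern recognition genes, 24 rose (24 adjusted over the list alone), median log2 change 1.56 (camera adjusted p = 9.7e-09, adjusted p = 0.246 with an estimated correlation), with 23 rises and 1 fall under upper-quartile scaling. Among 31 WRKY genes, 29 rose (29 adjusted over the list alone) and the median log2 change was 2.62 (camera adjusted p = 1.3e-11, adjusted p = 0.188 with an estimated correlation). The 24 antifungal protein genes had a median log2 change of 2.18 (camera adjusted p = 1.1e-07, adjusted p = 0.188 with an estimated correlation), and 21 rose (21 adjusted over the list alone). Of 35 detoxification genes, 30 rose (30 adjusted over the list alone), median log2 change 2.38 (camera adjusted p = 3.3e-09, adjusted p = 0.188 with an estimated correlation). Among 13 touch and wound genes, 10 rose (10 adjusted over the list alone) and the median log2 change was 2.49 (camera adjusted p = 7.5e-04, adjusted p = 0.188 with an estimated correlation).

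Photosynthesis genes moved the other way, by smaller steps. PSBS (AT1G44575), needed to shed excess light as heat, fell from 1213 ± 81.3 to 526 ± 31.2 CPM (-1.21 ± 0.08), and the photosystem I gene PSAN (AT5G64040) by a like amount (-1.12 ± 0.07). The Calvin cycle gene SBPASE (AT3G55800) and the chlorophyll synthesis genes PCB2 (AT5G18660) and CRD1 (AT3G56940) measured -1.25 ± 0.08, -1.17 ± 0.06 and -0.89 ± 0.07. Values of RBCS1B (AT5G38430) (-1.49 ± 0.08), RBCS2B (AT5G38420) (-1.50 ± 0.08) and LHCB1.3 (AT1G29930) (-1.12 ± 0.08) are uncertain, since each has near-identical copies. The senescence marker SAG13 (AT2G29350) rose by 5.32 ± 0.33. In the circadian clock list COL2 (AT3G02380) fell (-1.78 ± 0.08) and the evening gene TOC1 (AT5G61380) rose by 1.49 ± 0.11. Growth genes fell, such as the expansin gene EXPA5 (AT3G29030) (-2.12 ± 0.08). The largest adjusted p among these 9 genes was 2.9e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg), with no overlap between groups. The plastid read share was 2.97% in Alternaria and 4.06% in mock leaves. It was also lower in mock than in untreated leaves (5.51%), where 12 light harvesting genes rose and 3 fell. The share thus did not always follow these genes. Of 48 light harvesting and photosystem genes, 47 fell (47 adjusted over the list alone), median log2 change -0.77 (camera adjusted p = 1.8e-16, adjusted p = 0.188 with an estimated correlation). Among 19 Calvin cycle genes, 1 rose and 17 fell (1 and 17 adjusted over the list alone) and the median log2 change was -0.84 (camera adjusted p = 7.8e-08, adjusted p = 0.188 with an estimated correlation). The 14 chlorophyll synthesis genes had a median log2 change of -0.69 (camera adjusted p = 6.0e-06, adjusted p = 0.188 with an estimated correlation), and 12 fell (12 adjusted over the list alone). Of 18 senescence genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone), median log2 change 2.04 (camera adjusted p = 6.2e-06, adjusted p = 0.188 with an estimated correlation), with 16 rises and 2 falls under upper-quartile scaling. Among 26 clock genes, 6 rose and 9 fell (6 and 9 adjusted over the list alone) and the median log2 change was -0.14 (camera adjusted p = 0.303, adjusted p = 0.651 with an estimated correlation), with a median of -0.32 under upper-quartile scaling. The 23 growth and auxin genes had a median log2 change of -0.73 (camera adjusted p = 1.9e-04, adjusted p = 0.188 with an estimated correlation), and 1 rose and 15 fell (1 and 15 adjusted over the list alone), with 0 rises and 15 falls under upper-quartile scaling. The growth and auxin genes had 0 rises in 3 of 9 leave-outs.

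Phenylpropanoid genes, the source of lignin and flavonoids, split. The lignin gene CAD5 (AT4G34230) rose by 1.51 ± 0.11 while 4CL3 (AT1G65060), on the flavonoid side, fell (-1.70 ± 0.10). The anthocyanin regulator PAP1 (AT1G56650) and the first flavonoid enzyme gene CHS (AT5G13930) measured -1.69 ± 0.23 and -1.19 ± 0.12. Abscisic acid genes also went both ways, with the cold and drought gene COR15A (AT2G42540) at -1.71 ± 0.20 and the hormone-degrading enzyme gene CYP707A3 (AT5G45340) at 1.62 ± 0.26. All 6 passed edgeR's quasi-likelihood test, with a largest Benjamini-Hochberg adjusted p of 1.7e-04, with no overlap between groups. Of 17 phenylpropanoid genes, 8 rose and 6 fell (8 and 6 adjusted over the list alone), median log2 change 0.14 (camera adjusted p = 0.776, adjusted p = 0.897 with an estimated correlation), with a median of -0.04 under upper-quartile scaling. Among 16 flavonoid genes, 1 rose and 8 fell (1 and 8 adjusted over the list alone) and the median log2 change was -0.60 (camera adjusted p = 0.00470, adjusted p = 0.188 with an estimated correlation), with 0 rises and 10 falls under upper-quartile scaling. The 26 abscisic acid genes had a median log2 change of -0.15 (camera adjusted p = 0.419, adjusted p = 0.851 with an estimated correlation), and 5 rose and 10 fell (5 and 10 adjusted over the list alone), with a median of -0.33 under upper-quartile scaling. The flavonoid genes had 0 rises in 4 of 9 leave-outs.

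Genes of the small RNA machinery changed little, and both ways. The RNA polymerase gene RDR1 (AT1G14790) rose by 1.15 ± 0.09, AGO4 (AT2G27040) fell (-0.87 ± 0.09), and AGO2 (AT1G31280) rose by 0.45 ± 0.08. AGO1 (AT1G48410), which carries most microRNAs, was at 162 ± 8.23 CPM in Alternaria and 163 ± 2.32 CPM in mock leaves (-0.01 ± 0.07, edgeR Benjamini-Hochberg adjusted p = 0.941), and DCL1 (AT1G01040), which processes microRNA precursors, measured 0.04 ± 0.09 (edgeR Benjamini-Hochberg adjusted p = 0.763). Among genes targeted by microRNAs, PXMT1 (AT1G66700) and FAMT (AT3G44860), methyltransferase genes targeted by miR163, rose by 5.35 ± 0.33 and 2.22 ± 0.16, and NAC092 (AT5G39610), a senescence regulator targeted by miR164, rose by 3.01 ± 0.23. By family, 4 of 4 measured miR319 targets and 4 of 6 miR172 targets fell, 5 of 9 miR156 targets fell and 2 rose, and 4 of 6 miR164 targets rose and 1 fell (edgeR, Benjamini-Hochberg). Of the precursor transcripts MIR163 (AT1G66725) rose by 1.85 ± 0.24 and TAS1B (AT1G50055) fell (-0.89 ± 0.12). The strand setting of the counting is not given, so reads of precursors that lie in or beside other genes are uncertain. Each of these 8 genes had a Benjamini-Hochberg adjusted p of at most 3.0e-04 in edgeR's quasi-likelihood test, with no overlap between groups. Of 29 small RNA machinery genes, 8 rose and 8 fell (8 and 8 adjusted over the list alone), median log2 change 0.02 (camera adjusted p = 0.902, adjusted p = 0.897 with an estimated correlation), with a median of -0.16 under upper-quartile scaling. Among 105 microRNA target genes, 28 rose and 26 fell (27 and 25 adjusted over the list alone) and the median log2 change was 0.04 (camera adjusted p = 0.902, adjusted p = 0.897 with an estimated correlation), with a median of -0.14 under upper-quartile scaling. The 17 precursor genes had a median log2 change of -0.49 (camera adjusted p = 0.0155, adjusted p = 0.211 with an estimated correlation), and 1 rose and 8 fell (1 and 8 adjusted over the list alone).

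Camera called no cell type marker list. The guard cell genes MYB60 (AT1G08810) and KAT1 (AT5G46240) went apart (-1.02 ± 0.12 and 0.73 ± 0.10), the epidermis regulator ATML1 (AT4G21750) fell (-0.87 ± 0.07), and so did the xylem protease gene XCP1 (AT4G35350) (-0.79 ± 0.15). The flower gene AG (AT4G18960) was at -0.79 ± 0.23, and among genes often used as references UBQ10 (AT4G05320) rose by 0.52 ± 0.10 and ACT2 (AT3G18780) measured -0.21 ± 0.06. In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p of these 5 genes reached at most 5.6e-04, with no overlap between groups. Of 7 guard and myrosin cell markers, 1 rose and 4 fell (1 and 4 adjusted over the list alone), median log2 change -0.68 (camera adjusted p = 0.0999, adjusted p = 0.459 with an estimated correlation). Among 4 epidermis and trichome markers, 1 fell (1 adjusted over the list alone) and the median log2 change was -0.36 (camera adjusted p = 0.320, adjusted p = 0.439 with an estimated correlation). The 8 vascular markers had a median log2 change of -0.57 (camera adjusted p = 0.189, adjusted p = 0.628 with an estimated correlation), and 1 rose and 4 fell (1 and 5 adjusted over the list alone). Of 7 dividing cell and meristem markers, none passed, with 0 at an unadjusted p under 0.05 in edgeR (also none adjusted over the list alone), median log2 change -0.01 (camera adjusted p = 0.879, adjusted p = 0.897 with an estimated correlation), with 1 fall and a median of -0.18 under upper-quartile scaling. Among 2 root markers, none passed, with 0 at an unadjusted p under 0.05 in edgeR (also none adjusted over the list alone) and the median log2 change was -0.01, with a median of -0.19 under upper-quartile scaling. The 2 flower markers had a median log2 change of -0.83, and 1 fell (2 adjusted over the list alone), with 2 falls under upper-quartile scaling. Of 8 reference genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), median log2 change 0.02 (camera adjusted p = 0.816, adjusted p = 0.851 with an estimated correlation), with 2 rises, 3 falls and a median of -0.15 under upper-quartile scaling. AG did not pass edgeR (Benjamini-Hochberg) without mock replicate 2 (adjusted p = 0.0534). ACT2 did not pass edgeR (Benjamini-Hochberg) without Alternaria replicate 1 (adjusted p = 0.0519). The flower markers had 0 falls without mock replicate 2 and 2 falls without Alternaria replicate 1 and the reference genes had 0 falls without Alternaria replicate 1.

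Camera called 19 of the 30 lists with at least 3 measured members in Alternaria against mock, 12 up and 7 down. With an estimated correlation between genes it called 0, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.188. The rotation test fry (no comparison with other genes) called 25 of 30.

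**Figure D2:**
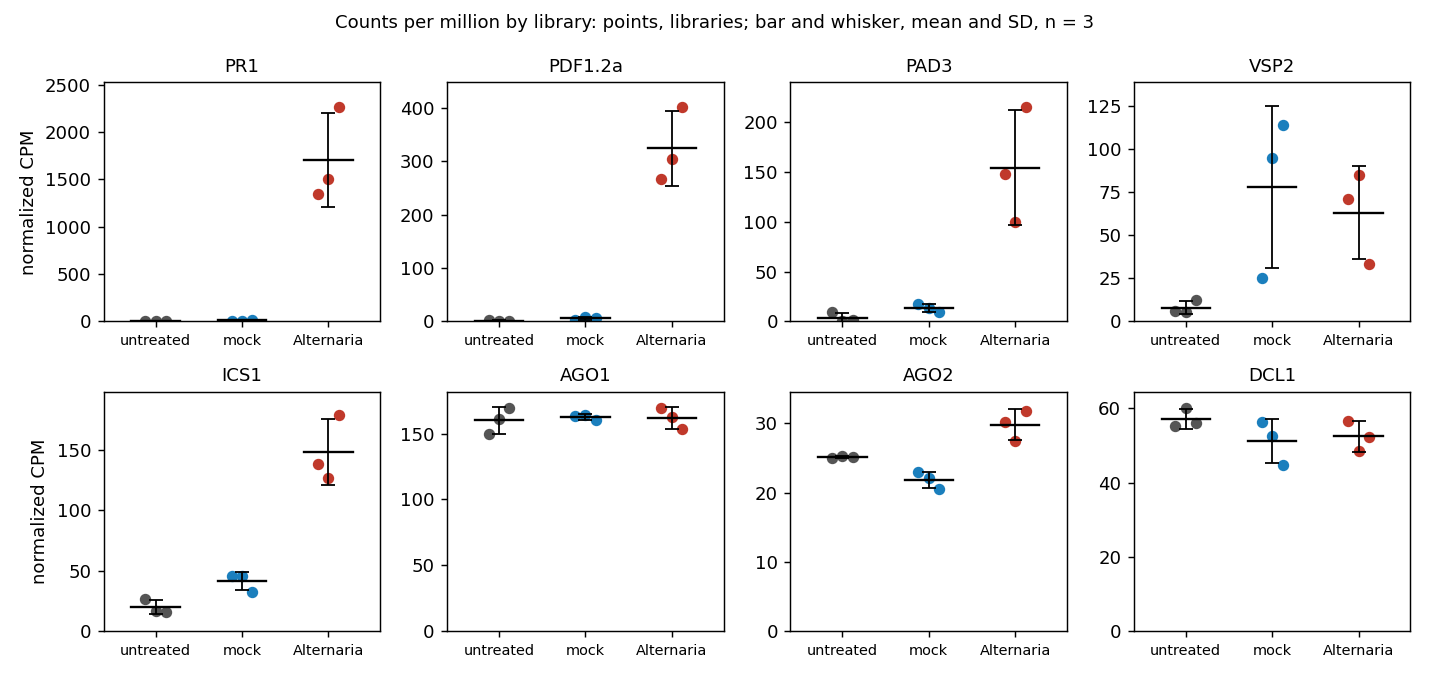
Normalized CPM (y axis) of PR1, PDF1.2a, PAD3, VSP2, ICS1, AGO1, AGO2 and DCL1 in untreated, mock and Alternaria leaves, 1 point per library, with bar and whisker for mean and SD (n = 3). PR1 went from 11.3 ± 4.69 CPM in mock to 1703 ± 496 CPM in Alternaria leaves.

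**Figure D3:**
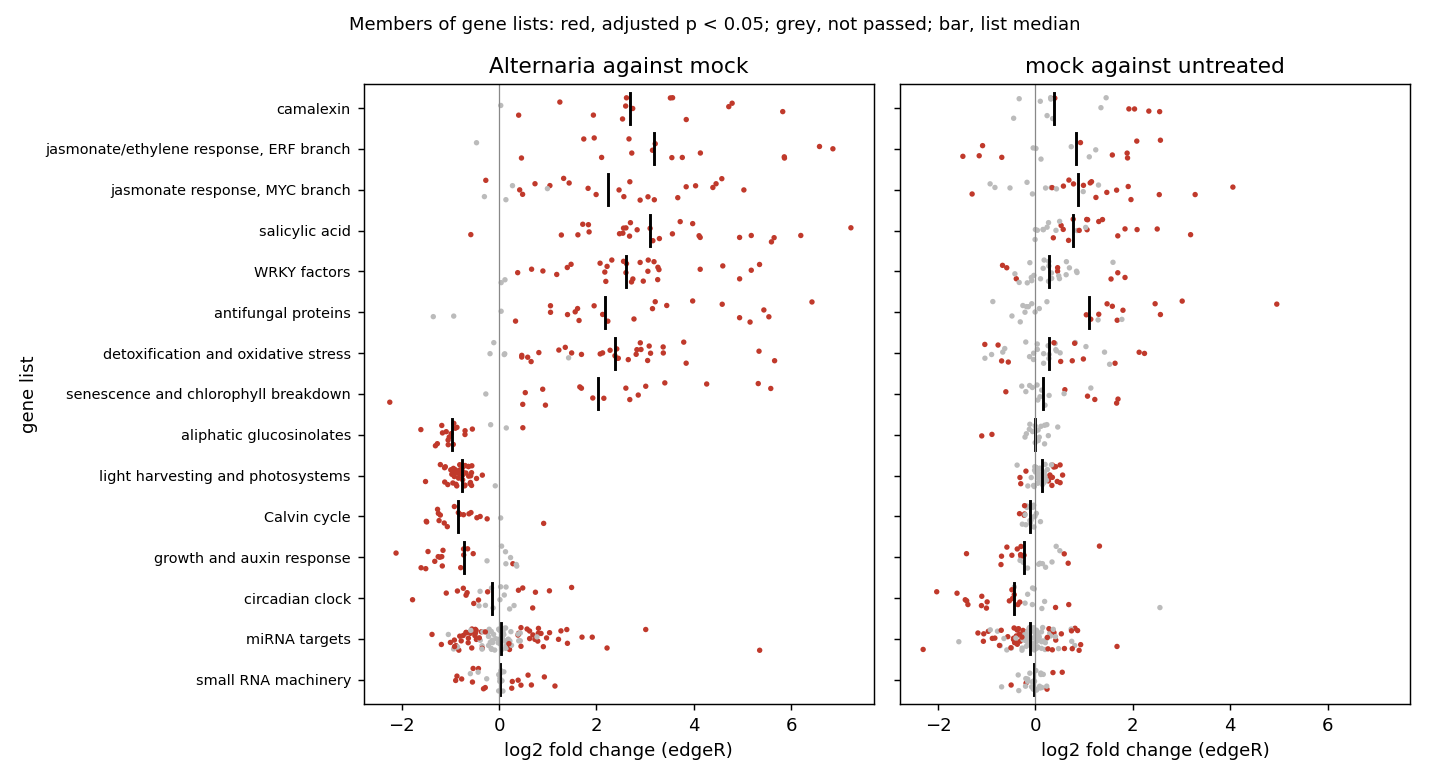
Log2 fold change (x axis) of the members of 15 gene lists in Alternaria against mock and in mock against untreated leaves, 1 point per gene, red where the adjusted p was under 0.05, with a bar at the list median. Medians were 3.18 and 0.83 for the branch shared by jasmonate and ethylene and -0.77 and 0.13 for light harvesting and photosystems.

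Alternaria against untreated asks how sprayed and infected leaves differ from leaves with no treatment, so it holds the spraying as well as the fungus. PR1 rose 306-fold (8.26 ± 0.45) and FMO1, needed for systemic resistance, 284-fold (8.15 ± 0.44). PME17 rose by 8.22 ± 0.30, from 1.25 ± 0.285 to 369 ± 133 CPM, and PDF1.2a by 7.75 ± 0.29. The cysteine protease gene AT2G27420 had the deepest fall, 64.5-fold (-6.01 ± 0.17), from 223 ± 46.6 CPM through 51.5 ± 5.43 CPM in mock leaves to 3.44 ± 0.219 CPM. AT3G15310.1, AT5G62730, AT4G34550 and AT3G24420 followed at -5.04 ± 0.24, -4.93 ± 0.18, -4.26 ± 0.21 and -4.21 ± 0.22. All 9 passed edgeR's quasi-likelihood test, with a largest Benjamini-Hochberg adjusted p of 1.1e-08, with no overlap between groups. PR1 was 8.86 without untreated replicate 1.

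Of 22019 genes 14288 (64.9%) passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, with 7287 up and 7001 down. Upper-quartile scaling, which moves the median of all genes by -0.196, gave 14783 with 5549 up and 9234 down. At least 2-fold changes numbered 5793 (3036 up, 2757 down), and at least 4-fold changes 1329 up and 323 down. The authors' deposited table had 12716 genes at an adjusted p under 0.05 (7012 up, 5704 down). Of these 12468 were also called by edgeR, with r = 0.997 across genes between the log2 changes of the authors' deposited table and edgeR.

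The camalexin gene PAD3 rose by 5.44 ± 0.63 and CYP82C2, of the neighbouring indole branch, by 5.38 ± 0.36. TSA1 rose by 2.48 ± 0.18 and IGMT1 by 3.54 ± 0.25. Jasmonate synthesis rose through LOX2 (AT3G45140) (2.83 ± 0.15) and AOC2 (AT3G25770) (2.92 ± 0.20), and here VSP2 did rise, by 2.98 ± 0.53, with JRG21 at 6.93 ± 0.32 and TAT3 at 6.54 ± 0.33. The salicylic acid genes DLO1 and ICS1 rose by 7.25 ± 0.29 and 2.92 ± 0.20. Each of these 11 genes had a Benjamini-Hochberg adjusted p of at most 3.0e-04 in edgeR's quasi-likelihood test, with no overlap between groups. Of 14 camalexin genes, 14 rose (14 adjusted over the list alone), median log2 change 4.83 (camera adjusted p = 4.2e-06, adjusted p = 0.217 with an estimated correlation). Among 10 tryptophan synthesis genes, 8 rose (8 up and 1 down adjusted over the list alone) and the median log2 change was 1.70 (camera adjusted p = 0.00766, adjusted p = 0.367 with an estimated correlation), with 7 rises and 2 falls under upper-quartile scaling. The 15 indole glucosinolate genes had a median log2 change of 1.00 (camera adjusted p = 0.0846, adjusted p = 0.464 with an estimated correlation), and 10 rose and 3 fell (10 and 3 adjusted over the list alone), with 7 rises and 5 falls under upper-quartile scaling. Of 20 aliphatic glucosinolate genes, 19 fell (19 adjusted over the list alone), median log2 change -0.97 (camera adjusted p = 4.3e-05, adjusted p = 0.368 with an estimated correlation). Among 13 jasmonate synthesis genes, 12 rose (12 adjusted over the list alone) and the median log2 change was 1.74 (camera adjusted p = 3.3e-05, adjusted p = 0.217 with an estimated correlation), with 11 rises and 1 fall under upper-quartile scaling. The 26 MYC-branch genes had a median log2 change of 2.61 (camera adjusted p = 2.2e-09, adjusted p = 0.217 with an estimated correlation), and 25 rose (25 adjusted over the list alone). Of 16 genes of the branch shared with ethylene, 15 rose (15 adjusted over the list alone), median log2 change 4.2 (camera adjusted p = 2.8e-06, adjusted p = 0.217 with an estimated correlation). Among 27 salicylic acid genes, 26 rose and 1 fell (26 and 1 adjusted over the list alone) and the median log2 change was 4.19 (camera adjusted p = 2.3e-11, adjusted p = 0.217 with an estimated correlation). PAD3 was 7.38 without untreated replicate 1 and 4.84 without untreated replicate 2. The indole glucosinolate genes had a camera adjusted p of 0.0212 without untreated replicate 1.

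NHL10 rose 219-fold (7.77 ± 0.32), WAKL10 by 5.12 ± 0.21, and WRKY75 and WRKY38 (AT5G22570) by 6.94 ± 0.39 and 5.82 ± 0.25. The glucanase gene AT4G16260 rose by 7.90 ± 0.32, AOX1D by 6.70 ± 0.34 and GSTU3 by 6.76 ± 0.46, and the touch gene WRKY40 by 2.76 ± 0.22. In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p of these 8 genes reached at most 2.2e-07, with no overlap between groups. Of 27 pattern recognition genes, 24 rose (24 adjusted over the list alone), median log2 change 1.88 (camera adjusted p = 4.9e-08, adjusted p = 0.286 with an estimated correlation), with 22 rises and 1 fall under upper-quartile scaling. Among 31 WRKY genes, 28 rose and 1 fell (29 and 1 adjusted over the list alone) and the median log2 change was 2.87 (camera adjusted p = 4.4e-10, adjusted p = 0.217 with an estimated correlation). The 24 antifungal protein genes had a median log2 change of 3.32 (camera adjusted p = 5.1e-08, adjusted p = 0.217 with an estimated correlation), and 21 rose (21 adjusted over the list alone). Of 35 detoxification genes, 29 rose and 1 fell (29 and 1 adjusted over the list alone), median log2 change 2.37 (camera adjusted p = 3.8e-08, adjusted p = 0.217 with an estimated correlation). Among 13 touch and wound genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone) and the median log2 change was 1.11 (camera adjusted p = 0.0473, adjusted p = 0.368 with an estimated correlation). The touch and wound genes had 1 fall in 4 of 9 leave-outs and a camera adjusted p of 0.0524 without Alternaria replicate 1.

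PSBS fell from 1513 ± 28.1 to 526 ± 31.2 CPM (-1.53 ± 0.08), SBPASE fell as well (-1.47 ± 0.08), and the chlorophyll genes PORB (AT4G27440) and GUN5 (AT5G13630) went apart (1.71 ± 0.16 and -1.25 ± 0.08). SAG13 rose by 6.99 ± 0.37. The morning clock genes CCA1 (AT2G46830) and LHY (AT1G01060) fell (-2.24 ± 0.09 and -2.09 ± 0.08), from 588 ± 60.3 and 701 ± 52.5 CPM in untreated leaves. Expansin genes fell, EXPA11 (AT1G20190) to -3.02 ± 0.21 and EXPA5 to -2.82 ± 0.08 on the log2 scale. The largest adjusted p among these 9 genes was 9.2e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg), with no overlap between groups. The plastid read share was 2.97% in Alternaria and 5.51% in untreated leaves. Of 48 light harvesting and photosystem genes, 42 fell (43 adjusted over the list alone), median log2 change -0.64 (camera adjusted p = 1.4e-10, adjusted p = 0.286 with an estimated correlation). Among 19 Calvin cycle genes, 1 rose and 16 fell (1 and 16 adjusted over the list alone) and the median log2 change was -1.01 (camera adjusted p = 3.4e-07, adjusted p = 0.217 with an estimated correlation). The 14 chlorophyll synthesis genes had a median log2 change of -0.79 (camera adjusted p = 8.2e-04, adjusted p = 0.217 with an estimated correlation), and 2 rose and 11 fell (2 and 11 adjusted over the list alone), with 1 rise and 12 falls under upper-quartile scaling. Of 18 senescence genes, 17 rose (17 adjusted over the list alone), median log2 change 2.00 (camera adjusted p = 3.3e-06, adjusted p = 0.217 with an estimated correlation). Among 26 clock genes, 6 rose and 15 fell (6 and 15 adjusted over the list alone) and the median log2 change was -0.66 (camera adjusted p = 0.00766, adjusted p = 0.286 with an estimated correlation). The 23 growth and auxin genes had a median log2 change of -0.91 (camera adjusted p = 0.00134, adjusted p = 0.217 with an estimated correlation), and 2 rose and 16 fell (2 and 16 adjusted over the list alone). The growth and auxin genes had 4 rises without untreated replicate 1 and 5 rises without Alternaria replicate 1.

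CAD5 rose by 1.99 ± 0.11 and 4CL3 fell (-3.37 ± 0.10), with the flavonol regulator MYB111 (AT5G49330), a target of miR858, at -3.22 ± 0.17 and the flavonoid glycosylation gene UGT78D2 (AT5G17050) at -2.36 ± 0.10. RDR1 rose by 1.70 ± 0.09 and AGO4 fell (-0.91 ± 0.10), while AGO1 (0.02 ± 0.07) did not pass and DCL1 (-0.12 ± 0.09) passed only under upper-quartile scaling (-0.32, edgeR Benjamini-Hochberg adjusted p = 0.0107). AGO2, the target of miR403, measured 0.25 ± 0.08 (edgeR Benjamini-Hochberg adjusted p = 0.0148) and did not pass under upper-quartile scaling (0.05, adjusted p = 0.594). The miR163 target PXMT1 and its precursor MIR163 both rose (6.16 ± 0.38 and 1.09 ± 0.24), NAC092 rose by 3.21 ± 0.24, the precursor TAS3 (AT3G17185) fell (-1.59 ± 0.12), and 3 of 3 miR858 targets and 3 of 3 miR397 targets fell (edgeR, Benjamini-Hochberg). All 10 passed edgeR's quasi-likelihood test, with a largest Benjamini-Hochberg adjusted p of 0.00145, with no overlap between groups. Of 17 phenylpropanoid genes, 5 rose and 9 fell (5 and 9 adjusted over the list alone), median log2 change -0.26 (camera adjusted p = 0.388, adjusted p = 0.713 with an estimated correlation), with a median of -0.46 under upper-quartile scaling. Among 16 flavonoid genes, 6 rose and 7 fell (6 and 7 adjusted over the list alone) and the median log2 change was -0.14 (camera adjusted p = 0.388, adjusted p = 0.571 with an estimated correlation), with a median of -0.33 under upper-quartile scaling. The 26 abscisic acid genes had a median log2 change of -5.0e-04 (camera adjusted p = 0.981, adjusted p = 0.993 with an estimated correlation), and 8 rose and 7 fell (8 and 7 adjusted over the list alone), with 5 rises, 10 falls and a median of -0.20 under upper-quartile scaling and a median of 0.00342 under RLE scaling. Of 29 small RNA machinery genes, 7 rose and 9 fell (6 and 9 adjusted over the list alone), median log2 change 0.02 (camera adjusted p = 0.887, adjusted p = 0.880 with an estimated correlation), with 4 rises, 14 falls and a median of -0.18 under upper-quartile scaling. Among 105 microRNA target genes, 29 rose and 42 fell (29 and 42 adjusted over the list alone) and the median log2 change was -0.12 (camera adjusted p = 0.437, adjusted p = 0.368 with an estimated correlation), with a median of -0.32 under upper-quartile scaling. The 17 precursor genes had a median log2 change of -0.25 (camera adjusted p = 0.571, adjusted p = 0.703 with an estimated correlation), and 4 rose and 3 fell (4 and 3 adjusted over the list alone), with 3 rises, 6 falls and a median of -0.45 under upper-quartile scaling. AGO2 did not pass edgeR (Benjamini-Hochberg) without Alternaria replicate 3 (adjusted p = 0.0564). PXMT1 was 6.78 without untreated replicate 1. The abscisic acid genes had 5 rises without untreated replicate 2 or untreated replicate 3 and the precursor genes had 5 falls without untreated replicate 3 or Alternaria replicate 1.

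Marker genes of several cell types were lower than in untreated leaves. MYB60 was at -1.11 ± 0.12, ATML1 and the epidermis gene PDF1 (AT2G42840) at -1.18 ± 0.07 and -1.02 ± 0.14, XCP1 at -1.46 ± 0.15, and the cell division genes CYCA1;1 (AT1G44110) and KNOLLE (AT1G08560) at -1.26 ± 0.18 and -1.19 ± 0.13. Among reference genes UBQ10 rose by 0.68 ± 0.10 and ACT2 fell (-0.68 ± 0.06). Each of these 8 genes had a Benjamini-Hochberg adjusted p of at most 5.2e-05 in edgeR's quasi-likelihood test, with no overlap between groups. Of 7 guard and myrosin cell markers, 1 rose and 4 fell (1 and 5 adjusted over the list alone), median log2 change -0.58 (camera adjusted p = 0.0813, adjusted p = 0.390 with an estimated correlation). Among 4 epidermis and trichome markers, 3 fell (3 adjusted over the list alone) and the median log2 change was -1.10 (camera adjusted p = 0.0858, adjusted p = 0.256 with an estimated correlation). The 8 vascular markers had a median log2 change of -1.17 (camera adjusted p = 0.0272, adjusted p = 0.368 with an estimated correlation), and 1 rose and 6 fell (1 and 6 adjusted over the list alone), with 0 rises and 7 falls under upper-quartile scaling. Of 7 dividing cell and meristem markers, 5 fell (5 adjusted over the list alone), median log2 change -0.60 (camera adjusted p = 0.0495, adjusted p = 0.349 with an estimated correlation). Among 2 root markers, none passed, with 0 at an unadjusted p under 0.05 in edgeR (also none adjusted over the list alone) and the median log2 change was -0.29, with 1 fall and a median of -0.48 under upper-quartile scaling. The 2 flower markers had a median log2 change of -0.62, and 1 fell (1 adjusted over the list alone). Of 8 reference genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), median log2 change 0.10 (camera adjusted p = 0.578, adjusted p = 0.633 with an estimated correlation), with 2 rises, 3 falls and a median of -0.10 under upper-quartile scaling. Camera called 20 of 30 lists in Alternaria against untreated, 12 up and 8 down. With an estimated correlation it called 0, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.217, and fry called 28. The guard and myrosin cell markers had a camera adjusted p of 0.0392 without untreated replicate 1 and the epidermis and trichome markers had a camera adjusted p of 0.0355 without untreated replicate 1. The vascular markers had 0 rises without untreated replicate 2 or Alternaria replicate 3 and the dividing cell and meristem markers had a camera adjusted p of 0.0512 to 0.0919 in 5 of 9 leave-outs. The flower markers had 0 falls in 3 of 9 leave-outs and the reference genes had 2 falls without Alternaria replicate 2.

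Mock against untreated asks what the mock treatment did without the fungus, if harvest times (not given) matched. The phosphatase gene AT1G14250 rose 14.7-fold (3.88 ± 0.45), the starch-degrading amylase gene BAM5 (AT4G15210) 12.1-fold (3.60 ± 0.29) and the wound marker VSP2 9.71-fold (3.28 ± 0.53). BAM5 stood at 15.3 ± 2.06 CPM in untreated, 185 ± 53.9 CPM in mock and 47.5 ± 17.4 CPM in Alternaria leaves. The scaffold gene BT1 (AT5G63160) fell 5.71-fold (-2.51 ± 0.10), from 173 ± 5.17 to 30.3 ± 5.08 CPM, followed by AT5G54130 (-2.40 ± 0.12), ABCI21 (AT5G44110) (-2.36 ± 0.08), AT4G34550 (-2.33 ± 0.18), the flavonol regulator MYB111 (-2.31 ± 0.15) and AT3G24420 (-2.29 ± 0.18). In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p of these 9 genes reached at most 8.2e-04, with no overlap between groups. PR1 measured 1.03 ± 0.39 with an adjusted p of 0.0653 (edgeR, Benjamini-Hochberg). PR1 passed at 1.64 without untreated replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.00555).

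Between mock and untreated leaves 6442 of 22019 genes (29.3%) passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 3332 up and 3110 down. Upper-quartile scaling, which moves the median of all genes by -0.0215, gave 6436 with 3064 up and 3372 down. At least 2-fold changes numbered 1090 (514 up, 576 down), and at least 4-fold changes 88 up and 50 down. Without untreated replicate 2 the count of changed genes was 4343. The authors' deposited table had 6068 genes at an adjusted p under 0.05 (3291 up, 2777 down), and 5684 of these were also called by edgeR. Log2 changes of the authors' deposited table and edgeR had r = 0.940 across genes.

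Jasmonate synthesis genes rose without the fungus, AOC2 by 2.25 ± 0.19, LOX2 by 1.65 ± 0.14 and AOS (AT5G42650) by 1.17 ± 0.10, and TAT3 followed at 1.96 ± 0.29. Among defence genes PDF1.2a measured 1.88 ± 0.31, the chitin-binding protein gene HEL (AT3G04720) 2.57 ± 0.21, ICS1 1.07 ± 0.20 and WRKY38 1.69 ± 0.30. All 8 passed edgeR's quasi-likelihood test, with a largest Benjamini-Hochberg adjusted p of 0.00183, with no overlap between groups. PAD3 measured 1.92 ± 0.63 (edgeR Benjamini-Hochberg adjusted p = 0.0379). Of 14 camalexin genes, 5 rose (6 adjusted over the list alone), median log2 change 0.38 (camera adjusted p = 0.0194, adjusted p = 0.644 with an estimated correlation). Among 10 tryptophan synthesis genes, 4 rose (4 adjusted over the list alone) and the median log2 change was 0.38 (camera adjusted p = 0.0194, adjusted p = 0.588 with an estimated correlation). The 15 indole glucosinolate genes had a median log2 change of 0.23 (camera adjusted p = 0.273, adjusted p = 0.703 with an estimated correlation), and 3 rose and 2 fell (4 and 2 adjusted over the list alone). Of 20 aliphatic glucosinolate genes, 2 fell (2 adjusted over the list alone), median log2 change -0.00311 (camera adjusted p = 0.890, adjusted p = 0.970 with an estimated correlation), with a median of -0.02 under upper-quartile scaling and a median of 0.00375 under RLE scaling. Among 13 jasmonate synthesis genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone) and the median log2 change was 0.61 (camera adjusted p = 0.00382, adjusted p = 0.588 with an estimated correlation). The 26 MYC-branch genes had a median log2 change of 0.88 (camera adjusted p = 2.1e-04, adjusted p = 0.588 with an estimated correlation), and 15 rose and 1 fell (17 and 2 adjusted over the list alone), with 14 rises and 2 falls under upper-quartile scaling. PAD3 was 3.86 without untreated replicate 1. PAD3 did not pass edgeR (Benjamini-Hochberg) without untreated replicate 2 (adjusted p = 0.115) or without untreated replicate 3 (adjusted p = 0.132) or without mock replicate 1 (adjusted p = 0.0939) or without mock replicate 2 (adjusted p = 0.0820). The camalexin genes had 2 to 3 rises in 3 of 9 leave-outs and 8 rises without untreated replicate 1 and a camera adjusted p of 0.0518 without untreated replicate 2 and 0.0515 without untreated replicate 3 and the tryptophan synthesis genes had 1 to 2 rises in 3 of 9 leave-outs and a camera adjusted p of 0.0555 without untreated replicate 3. The indole glucosinolate genes had 7 rises without untreated replicate 1 and 0 to 1 fall in 5 of 9 leave-outs and a camera adjusted p of 0.0339 without untreated replicate 1 and the jasmonate synthesis genes had 0 to 1 fall in 5 of 9 leave-outs. The MYC-branch genes had 3 falls without untreated replicate 1 and 2 falls without Alternaria replicate 3.

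NHL10 rose by 2.33 ± 0.45, and the glutathione transferase gene GSTF2 (AT4G02520) rose by 1.63 ± 0.30, while the stress regulator ATAF1 (AT1G01720) fell (-1.04 ± 0.13). Each of these 3 genes had a Benjamini-Hochberg adjusted p of at most 0.00265 in edgeR's quasi-likelihood test, with no overlap between groups. Of 16 genes of the branch shared with ethylene, 6 rose and 4 fell (7 and 4 adjusted over the list alone), median log2 change 0.83 (camera adjusted p = 0.157, adjusted p = 0.703 with an estimated correlation). Among 27 salicylic acid genes, 16 rose (19 adjusted over the list alone) and the median log2 change was 0.78 (camera adjusted p = 1.1e-05, adjusted p = 0.588 with an estimated correlation). The 27 pattern recognition genes had a median log2 change of 0.32 (camera adjusted p = 0.0341, adjusted p = 0.703 with an estimated correlation), and 11 rose and 2 fell (12 and 3 adjusted over the list alone). Of 31 WRKY genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone), median log2 change 0.28 (camera adjusted p = 0.0702, adjusted p = 0.703 with an estimated correlation). Among 24 antifungal protein genes, 11 rose (12 adjusted over the list alone) and the median log2 change was 1.09 (camera adjusted p = 0.00455, adjusted p = 0.588 with an estimated correlation), with 11 rises and 1 fall under upper-quartile scaling. The 35 detoxification genes had a median log2 change of 0.28 (camera adjusted p = 0.177, adjusted p = 0.703 with an estimated correlation), and 8 rose and 4 fell (8 and 4 adjusted over the list alone). GSTF2 was 2.23 without untreated replicate 1. The genes of the branch shared with ethylene had 3 rises without untreated replicate 2 and the salicylic acid genes had 9 rises without untreated replicate 2 or untreated replicate 3. The pattern recognition genes had 6 rises without untreated replicate 2 and 7 rises without untreated replicate 3 and 1 fall in 3 of 9 leave-outs and a camera adjusted p of 0.0622 to 0.119 in 3 of 9 leave-outs and the WRKY genes had 11 rises without untreated replicate 1 and 9 rises without Alternaria replicate 3 and 5 falls without untreated replicate 2 and a camera adjusted p of 0.00112 without untreated replicate 1 and 0.0371 without mock replicate 3. The detoxification genes had 3 to 5 rises in 4 of 9 leave-outs and a camera adjusted p of 0.0340 without untreated replicate 1.

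Clock genes fell. RVE1 (AT5G17300) was at -2.03 ± 0.15, RVE8 (AT3G09600) at -1.44 ± 0.09, LHY at -1.41 ± 0.08 and GI (AT1G22770) at -1.61 ± 0.12, and LHY went from 701 ± 52.5 CPM in untreated to 263 ± 14.2 CPM in mock leaves. The touch genes ZAT10 (AT1G27730) and CML24 (AT5G37770) fell (-1.67 ± 0.26 and -0.75 ± 0.12), opposite to their list with the fungus. EXPA11 fell (-1.42 ± 0.20) and the growth regulator PIF4 (AT2G43010) rose by 1.31 ± 0.11. 4CL3 and PAL1 (AT2G37040), the entry of the phenylpropanoid pathway, fell (-1.67 ± 0.09 and -0.87 ± 0.10), and the flavonoid list split between PAP1 (3.01 ± 0.26) and MYB111 (-2.31 ± 0.15). In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p of these 12 genes reached at most 6.7e-04, with no overlap between groups. Of 26 clock genes, 2 rose and 15 fell (2 and 15 adjusted over the list alone), median log2 change -0.44 (camera adjusted p = 5.6e-05, adjusted p = 0.588 with an estimated correlation). Among 13 touch and wound genes, 4 fell (4 adjusted over the list alone) and the median log2 change was -0.63 (camera adjusted p = 0.0176, adjusted p = 0.588 with an estimated correlation). The 23 growth and auxin genes had a median log2 change of -0.23 (camera adjusted p = 0.224, adjusted p = 0.703 with an estimated correlation), and 3 rose and 10 fell (5 and 10 adjusted over the list alone). Of 17 phenylpropanoid genes, 2 rose and 9 fell (3 and 10 adjusted over the list alone), median log2 change -0.27 (camera adjusted p = 0.0167, adjusted p = 0.588 with an estimated correlation). Among 16 flavonoid genes, 7 rose and 5 fell (8 and 6 adjusted over the list alone) and the median log2 change was 0.22 (camera adjusted p = 0.822, adjusted p = 0.858 with an estimated correlation). The touch and wound genes had a camera adjusted p of 0.0771 without untreated replicate 3 and the growth and auxin genes had 6 falls in 3 of 9 leave-outs.

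**Figure D4:**
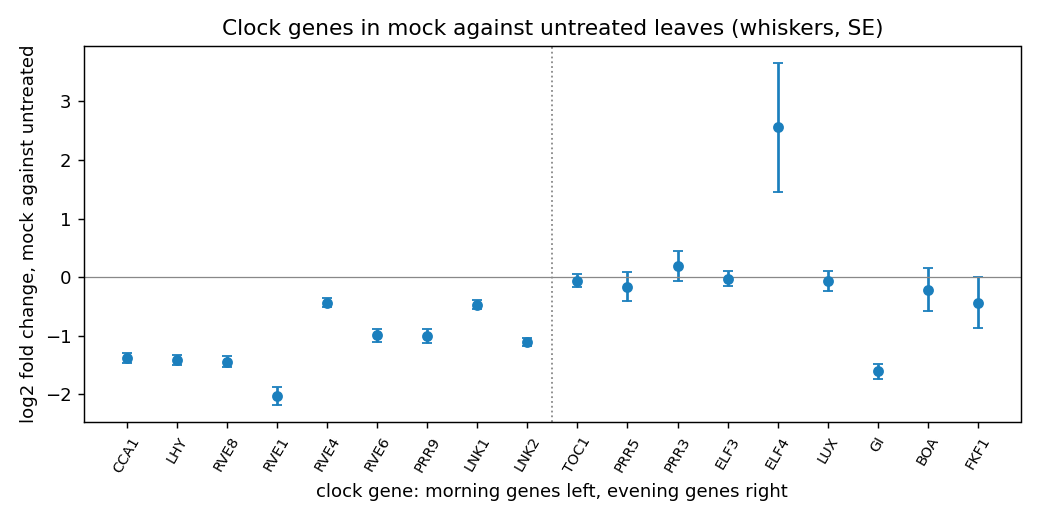
Log2 fold change (y axis) of clock genes in mock against untreated leaves, morning genes left and evening genes right, 1 point per gene with its SE (n = 3 per group). All 9 morning genes fell, and of the evening genes GI fell (-1.61) and 0 rose in edgeR's test.

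Photosynthesis genes moved little. PSAD2 (AT1G03130) rose by 0.56 ± 0.07, the Rubisco activase gene RCA (AT2G39730) fell (-0.33 ± 0.08), and the chlorophyll genes PORB and CAO (AT1G44446) rose by 1.46 ± 0.16 and 0.69 ± 0.08 where GUN5 fell (-0.52 ± 0.07). The abscisic acid phosphatase gene HAI2 (AT1G07430) rose by 1.93 ± 0.36 and CYP707A3 fell (-1.97 ± 0.26). The largest adjusted p among these 7 genes was 0.00665 (edgeR quasi-likelihood test, Benjamini-Hochberg), with no overlap between groups. The plastid read share was 4.06% in mock and 5.51% in untreated leaves. Of 48 light harvesting and photosystem genes, 12 rose and 3 fell (14 and 4 adjusted over the list alone), median log2 change 0.13 (camera adjusted p = 0.0115, adjusted p = 0.703 with an estimated correlation). Among 19 Calvin cycle genes, 4 fell (1 adjusted over the list alone) and the median log2 change was -0.11 (camera adjusted p = 0.0399, adjusted p = 0.703 with an estimated correlation), and with RLE scaling its camera adjusted p was 0.0534, with 2 falls under RLE scaling. The 14 chlorophyll synthesis genes had a median log2 change of -0.10 (camera adjusted p = 0.649, adjusted p = 0.822 with an estimated correlation), and 4 rose and 4 fell (4 and 6 adjusted over the list alone). Of 18 senescence genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), median log2 change 0.16 (camera adjusted p = 0.105, adjusted p = 0.703 with an estimated correlation). Among 26 abscisic acid genes, 10 rose and 6 fell (11 and 6 adjusted over the list alone) and the median log2 change was 0.46 (camera adjusted p = 0.187, adjusted p = 0.703 with an estimated correlation). The light harvesting and photosystem genes had 7 rises without untreated replicate 2 or mock replicate 2 and 1 fall without untreated replicate 3 or mock replicate 3 and the Calvin cycle genes had 1 fall in 5 of 9 leave-outs and a camera adjusted p of 0.0511 to 0.134 in 6 of 9 leave-outs. The chlorophyll synthesis genes had 1 to 2 falls in 3 of 9 leave-outs and the senescence genes had 8 rises without untreated replicate 1 and a camera adjusted p of 0.0483 without mock replicate 1. The abscisic acid genes had a camera adjusted p of 0.0451 without untreated replicate 1 and 0.0483 without mock replicate 1.

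In the small RNA machinery RDR1 and the microRNA processing gene HYL1 (AT1G09700) rose by 0.55 ± 0.09 and 0.36 ± 0.07 and DCL4 (AT5G20320) fell (-0.50 ± 0.07), while AGO1 (0.02 ± 0.07), AGO2 (-0.20 ± 0.08) and DCL1 (-0.16 ± 0.09) did not pass. The miR171 target SCL6 (AT4G00150) fell (-1.07 ± 0.08), with 2 of 3 miR171 targets, 3 of 5 miR166 targets and 3 of 3 miR397 targets lower and 3 of 7 miR169 targets higher (edgeR, Benjamini-Hochberg). The precursor transcripts MIR825 (AT2G26211) and AT4G13495 rose by 1.38 ± 0.26 and 1.32 ± 0.08, and TAS3 fell (-0.91 ± 0.11). All 7 passed edgeR's quasi-likelihood test, with a largest Benjamini-Hochberg adjusted p of 0.00390, with no overlap between groups. Of 29 small RNA machinery genes, 3 rose and 2 fell (2 and 1 adjusted over the list alone), median log2 change -0.04 (camera adjusted p = 0.822, adjusted p = 0.841 with an estimated correlation), with a median of -0.06 under upper-quartile scaling and 3 rises and 1 fall under RLE scaling. Among 105 microRNA target genes, 16 rose and 26 fell (16 and 29 adjusted over the list alone) and the median log2 change was -0.12 (camera adjusted p = 0.149, adjusted p = 0.588 with an estimated correlation). The 17 precursor genes had a median log2 change of 0.41 (camera adjusted p = 0.157, adjusted p = 0.588 with an estimated correlation), and 5 rose and 2 fell (5 and 2 adjusted over the list alone). The small RNA machinery genes had 1 fall with each library left out and the microRNA target genes had 7 rises without untreated replicate 2 and 8 rises without mock replicate 3. The precursor genes had 1 fall in 6 of 9 leave-outs.

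PDF1 and ATML1 of the epidermis measured -1.13 ± 0.14 and -0.31 ± 0.07, XCP1 and the phloem regulator APL (AT1G79430) -0.67 ± 0.14 and -0.61 ± 0.11, CYCA1;1 and KNOLLE -1.02 ± 0.17 and -0.96 ± 0.13, and ACT2 -0.46 ± 0.06. Each of these 7 genes had a Benjamini-Hochberg adjusted p of at most 0.00545 in edgeR's quasi-likelihood test, with no overlap between groups. Of 7 guard and myrosin cell markers, none passed, with 2 at an unadjusted p under 0.05 in edgeR (also none adjusted over the list alone), median log2 change -0.15 (camera adjusted p = 0.273, adjusted p = 0.703 with an estimated correlation). Among 4 epidermis and trichome markers, 2 fell (2 adjusted over the list alone) and the median log2 change was -0.65 (camera adjusted p = 0.105, adjusted p = 0.588 with an estimated correlation). The 8 vascular markers had a median log2 change of -0.55 (camera adjusted p = 0.00733, adjusted p = 0.588 with an estimated correlation), and 6 fell (7 adjusted over the list alone). Of 7 dividing cell and meristem markers, 4 fell (5 adjusted over the list alone), median log2 change -0.67 (camera adjusted p = 0.00455, adjusted p = 0.588 with an estimated correlation). Among 2 root markers, none passed, with 0 at an unadjusted p under 0.05 in edgeR (also none adjusted over the list alone) and the median log2 change was -0.27. The 2 flower markers had a median log2 change of 0.21, and 1 rose (1 adjusted over the list alone), with 0 rises under upper-quartile scaling. Of 8 reference genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone), median log2 change 0.14 (camera adjusted p = 0.731, adjusted p = 0.765 with an estimated correlation). Camera called 14 of 30 lists in mock against untreated, 8 up and 6 down. With an estimated correlation it called 0, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.588. Fry called 12 and, of the lists called by camera, missed camalexin (adjusted p = 0.0887), tryptophan synthesis (0.0685), pattern recognition (0.156), light harvesting (0.120) and the Calvin cycle (0.0860). The epidermis and trichome markers had a camera adjusted p of 0.0350 without untreated replicate 1 and the flower markers had 0 rises in 8 of 9 leave-outs. The reference genes had 0 rises in 5 of 9 leave-outs.

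Genes that rose in mock against untreated leaves tended to rise in Alternaria against untreated leaves too. LOX2, for example, stood at 244 ± 27.1 CPM in untreated, 765 ± 159 CPM in mock and 1734 ± 159 CPM in Alternaria leaves (mean ± SD, n = 3). Against the same untreated libraries, 2444 genes rose and 2396 fell in both comparisons (edgeR, Benjamini-Hochberg), where independent lists of these sizes give 1103 and 989, and 505 went opposite ways against 2089. Across genes the log2 changes had r = 0.612, against 0.526 in 20 simulations of unchanged groups that share the untreated libraries, and a covariance of 0.406 against 0.0288, a difference of 0.377. With the untreated libraries divided so that none was shared, r was 0.377 to 0.578 over 6 ways.

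Against both kinds of control 5673 genes rose and 4654 fell in Alternaria leaves, PR1, FMO1 and PME17 among the first and AT2G27420 and EXPA5 among the second, where independent lists give 2147 and 1829. Opposite calls numbered 179 against 3967. These comparisons share the Alternaria libraries. Log2 changes had r = 0.900 across genes (0.488 in simulations without effects) and a covariance of 1.08 (0.0261).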

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

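Alternatives were chosen before the data were examined, except list counts without untreated replicate 1. With a fold limit of 2 the changed genes numbered 3752, 5793 and 1090 (Alternaria against mock, Alternaria against untreated, mock against untreated). With an estimated correlation camera called 0, 0 and 0 lists (2, 1 and 1 at an unadjusted p under 0.05; fry called 25, 28 and 12), and the cause was not tested. Leaving out each library in turn gave 10824 to 12570, 12972 to 14286 and 4343 to 6644 changed genes, and 19 to 20, 18 to 23 and 9 to 18 called lists. Other settings kept the totals of changed genes within 1.5 times, with 11693 to 13051, 13445 to 14783 and 6020 to 6638 genes, and 0 calls of opposite sign. Upper-quartile scaling moved counts and medians of some lists further. A replicate block gave 11940, 13942 and 6020, lost the list call of dividing cell and meristem markers (adjusted p = 0.0573, Alternaria against untreated) and gained that of WRKY factors (0.0445, mock against untreated). Replicate numbers did not pair samples: same-number correlations were -0.0652 to 0.0341 over 9 pairs, with 0 over 0.1. Of genes the naming rule chose, 123 of 128, 122 of 131 and 92 of 123 kept their call under all settings, and 0 reversed. Counts of calls shared by comparisons stayed within 1.5 times with DESeq2, the block and RLE. At these depths a change of 1.5-fold is missed in about as many genes as it is found.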

Other observations

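Families of related genes were grouped by annotation words after the list results were seen, and 35 were tested with camera in all comparisons. With Alternaria against mock, receptor families rose: 29 of 35 cysteine-rich receptor kinase genes (4 fell; CRK39 by 4.24 ± 0.27 and CRK7 by 4.13 ± 0.32 on the log2 scale; camera adjusted p = 2.2e-05, adjusted p = 0.414 with an estimated correlation), and 58 of 80 TIR-NBS-LRR immune receptor genes (4 fell; AT5G41750 by 3.59 ± 0.12; adjusted p = 7.6e-11, adjusted p = 0.412 with an estimated correlation). Genes for folding proteins in the endoplasmic reticulum rose too (11 of 16, 2 fell, CRT3 by 2.63 ± 0.14; adjusted p = 0.00138, adjusted p = 0.412 with an estimated correlation). Expansin genes, which loosen walls for growth, fell in 12 of 20 (EXPB1 -2.34 ± 0.17; adjusted p = 3.8e-04, adjusted p = 0.188 with an estimated correlation). Counts of members are edgeR calls at a Benjamini-Hochberg adjusted p under 0.05.

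Ribosomal and proteasome genes also differed between mock and untreated leaves. Of 57 cytosolic ribosomal protein genes 21 rose and 1 fell in mock against untreated (median 0.21; camera adjusted p = 3.5e-05, adjusted p = 0.590 with an estimated correlation), and 3 rose and 35 fell in Alternaria against mock (median -0.26; adjusted p = 3.8e-04, adjusted p = 0.481 with an estimated correlation). These comparisons share the mock libraries, and in Alternaria against untreated 9 rose and 18 fell (median -0.07; adjusted p = 0.455, adjusted p = 0.862 with an estimated correlation). Under upper-quartile scaling the medians with Alternaria were -0.43 against mock and -0.26 against untreated. Proteasome genes rose in both, 22 of 47 with mock (PA200 by 0.85 ± 0.10; adjusted p = 8.7e-07, adjusted p = 0.447 with an estimated correlation) and 33 with the fungus, where 1 fell (median 0.28, or 0.11 under upper-quartile scaling; PA200 by 1.43 ± 0.10; adjusted p = 2.4e-05, adjusted p = 0.412 with an estimated correlation).

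Of the tests that follow, only the test of shared untreated libraries had its prediction written before its result was seen. On principal component 1 mock leaves lay part of the way from untreated to Alternaria leaves. RNA or spores of Alternaria samples mixed into the mock samples could give this, but mixing cannot carry a gene beyond its level in the source, and 24.2% of the genes higher in mock than in untreated (805 of 3332) were lower in Alternaria than in mock, which speaks against mixing as the whole cause. Chance values of the shared untreated libraries could give it as well, but with none shared the lowest r across genes was 0.377, which speaks against this. The treatment itself (handling and the mock liquid) and a different harvest time of mock and untreated plants stay open, since no group separates them.

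Morning clock genes were lower in mock than in untreated leaves, CCA1 by -1.39 ± 0.09 and RVE1 by -2.03 ± 0.15 on the log2 scale. 100% of the 9 fallen morning genes still fell with each untreated library left out, which speaks against 1 unusual one. A later harvest of mock leaves may have raised evening genes, but 0% of those called rose (only GI was called, which fell). Another harvest hour and an effect of the mock treatment on the clock both stay open. Harvest hour was not tested for Alternaria against mock.

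Targets of microRNAs changed with Alternaria in 54 of 105 genes (51.4%). Lists of 105 genes matched on expression changed in 57.1% (47.6% to 65.7%), which puts the targets at the 10.985 percentile of 10000 lists, and speaks against targets that changed more often than genes of like expression in this comparison. In Alternaria against untreated 67.6% changed (matched median 66.7%, percentile 61.8). In mock against untreated 42 of 105 changed, above the matched 30.5% (21.9% to 39.0%), at the 98.6 percentile. Targets moving against their precursor could show regulation by the microRNA, but only 33.3% of 3 changed targets with a changed precursor did so (families of miR163 and miR824), too few to decide. MIR824, on which it rests, did not pass edgeR (Benjamini-Hochberg) without mock replicate 1 (adjusted p = 0.0504) or Alternaria replicate 1 (0.0556).

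Each comparison was also made for the 10 ways to divide its 6 libraries into 3 and 3. In all comparisons 1 of 10 splits, the real one, gave as many changed genes (12241, 14288 and 6442 in edgeR, Benjamini-Hochberg), and the highest other split gave 0. At an unadjusted p under 0.05 edgeR gave 13205, 14995 and 9000 genes in the real split and at most 477, 702 and 1505 in the others. With 10 splits a share under 0.05 cannot be reached.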
